A study of Arabidopsis thaliana with 6 samples.

How the data were processed

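Messenger RNA was measured in whole Arabidopsis thaliana seedlings, 8 days old and grown in continuous light, from 3 libraries of Col-0 wild type and 3 libraries of the splicing factor mutant prp8a-14. Per the labels' protocols, RNA was enriched by poly-A selection, copied with random hexamers and sequenced in pairs on a NovaSeq instrument. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread featureCounts 1.4.6-p5, Salmon 0.8.2, edgeR and limma, with no role or order. The genome build and the annotation are not given in the sources used here, nor is whether the counting used strand, so antisense and overlapping genes are uncertain. The series design calls the libraries biological replicates.

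The deposited table of the whole series holds log2 expression values per library, and, per the file headers, the authors' own log2 fold change with its limits, p-value, adjusted p-value and a moderated statistic, which is a score. The deposited log2 values are log2 of CPM (counts scaled to a common library size) with 0.5 added to each count, relative to a scaled library size chosen by the authors. This was found from the values: with a tolerance of 0.1, 100% of them gave whole counts in each library. The table lists 20079 lines for 19807 genes, because 272 lines repeat a gene that has several Entrez numbers, and the repeats have equal values. Each gene was used once. The rule by which the authors chose the listed genes is not given in the sources used here. Another 3 columns of per-sample values matched no sample of the series and were not used. The authors' own fit and the scaled library sizes appear to have used them too. The fit's values are named as the authors' wherever they are printed, and the CPM values and fold changes of this report rest on those sizes, so library totals were also tried.

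Library depth was read from the recovered counts. Totals over the listed genes ran from 49126331 to 63069817, and 3 counts, the limit that a count of 0 allows, corresponded to 0.0484 to 0.0635 CPM. Intervals on counts are exact binomial intervals at 95% and cover counting error only. CPM values in the text are recovered counts over the authors' scaled library sizes.

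Genes were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance (eBayes), on the log2 values as deposited, for all 19807 genes and 6 libraries. Two-sided p-values were adjusted by the Benjamini-Hochberg method (BH), and genes with an adjusted p under 0.05 were called changed. Size was counted separately at 2-fold. This was the branch planned for log2 values; the branches planned for count tables did not apply. The fold change of a gene near 0 depends on the added 0.5 counts, and for named genes with under 15 counts in a library the ratio of pooled counts is given. Counts were simulated for the 19807 genes from the real means and library sizes of the mutant and wild type comparison, with 50 genes changed at each size. The fit recovered 84% of them at 1.25-fold, 96% at 1.5-fold, 100% at 2-fold and 100% at 4-fold. Of 199 calls 9 were of unchanged genes. Every gene was given the same dispersion (spread between replicates) of 0.00143, a median from the wild type libraries. Real spreads differ between genes and far more genes were called, so these rates need not hold for the real data.

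The 17 gene lists, the 5 lists defined by annotation, the rule for named genes and the alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, BH-adjusted over all 22 lists, with an estimated correlation and with fry beside it. Camera compares a list with all other genes; fry asks whether the list's genes move one way on balance. Members were also adjusted over the list alone. The named genes were PRP8A and PRP8B; from each list up to 2 members that rose and up to 2 that fell, by size among those past the threshold, or the member with the smallest p; the 10 largest rises and 10 largest falls among changed genes with a symbol, a mean of at least 5 CPM and groups that did not overlap; and the 5 smallest p under the same conditions. Of the genes this rule selected, 2 are not reported here. Other genes named in the text are list members or were chosen after their values were seen.

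Symbols came from the deposited table and, for 326 genes, from the gene table of the RefSeq annotation of assembly TAIR10.1, which held 19686 of the listed genes. That annotation also gave exon numbers (longest transcript) and gene order. No coordinates are printed, since the authors' build is not named. Rank correlations, tests of neighbouring genes and drawing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the rank and neighbour statistics were tested on simulated data.

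The alternatives were quantile normalization, a mean of at least 5 CPM, limma without the trend, pseudocounts of 0.1 and 1 CPM, the fit without organelle-encoded genes, and each library left out in turn. A fit with no filter was planned, but all listed genes were already in use. Alternatives added after seeing the data were limma's voom on the recovered counts, voom with sample quality weights, and library totals in place of the scaled library sizes.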

Results

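Poly-A selected RNA was compared between whole 8-day-old seedlings of Col-0 wild type and of prp8a-14, a line mutated in the gene of PRP8A, the central protein of the spliceosome. Each genotype had 3 biological replicates, numbered 1 to 3 in wild type and 4 to 6 in the mutant. Counts on the listed genes totalled 51693138, 50804951 and 54450545 in wild type and 58121291, 49126331 and 63069817 in prp8a-14. Within each genotype every pair of libraries differed beyond sampling noise, with a chi-square per degree of freedom of 8.01 to 15.8. The first principal component held 67.4% of the variance and separated the genotypes.

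The comparison asked which transcripts differ in level when PRP8A is mutated. PRP8A itself stood at 412 CPM ± 22.4 (SD, n = 3) in wild type and 501 CPM ± 35.5 (SD, n = 3) in the mutant, a log2 rise of 0.28 (SE 0.06, limma with BH, adjusted p = 0.0031), or 0.18 with library totals. Its level does not check the labels, since a mutation in the coding sequence need not change it. PRP8B, its closest relative, rose by 0.59 (adjusted p = 0.0038, limma with BH) from a far lower 4.37 CPM ± 0.453 (SD, n = 3), and reads shared between these similar genes leave its value uncertain. Of 19807 genes 6977 changed (35.2%), 3544 up and 3433 down, and 461 changed by at least 2-fold, 166 up and 295 down. Most shifts were small: 77.3% of changed genes moved by under 1.5-fold. The groups did not overlap for 48.1% of genes, against 10% by chance. With library totals in place of the authors' scaled sizes, 7964 genes changed, of which 26.5% rose against 50.8% with the scaled sizes, and 24.7% against 36.0% of the 2-fold changes rose. Library totals moved the median log2 change over all genes to -0.091, from 0.0037 with the scaled sizes.

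The largest rises among well-expressed named genes were mostly plastid genes and genes of plastid proteins. FKBP16-4, a nuclear gene of a thylakoid lumen immunophilin, rose from 47.8 CPM ± 2.03 to 224 CPM ± 9.33 (SD, n = 3), a log2 change of 2.23 with the smallest adjusted p of the named genes (3.2e-10, limma with BH). GPT2, a plastid glucose 6-phosphate transporter, rose by 1.77, and GA20OX2, an enzyme of gibberellin synthesis, by 1.68. CAF1-9, of a deadenylase family, rose by 1.48, although its wild type libraries varied widely (22.2 CPM ± 12.6, SD, n = 3). The largest falls among genes with a symbol and a mean of at least 5 CPM were CYP81D11, a cytochrome P450 (-3.54), the marneral synthase MRN1 (-3.29), ROSY1 (-3.24), MLP328 (-3.20), the tirucalladienol synthase PEN3 (-3.08), CYP716A2 (-2.85), the isochorismate synthase ICS2 (-2.69), the vegetative storage protein VSP1 (-2.61), the annexin ANNAT7 (-2.23) and FLZ7 (-2.17). MLP328 dropped from 166 CPM ± 13.7 to 18.1 CPM ± 2.88 (SD, n = 3). CLPR4, a subunit of the plastid Clp protease, RDL5, a cysteine protease, and ATDR4 were among the 5 smallest p, with log2 changes of -1.42, -1.71 and -1.51.

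**Figure D1:**
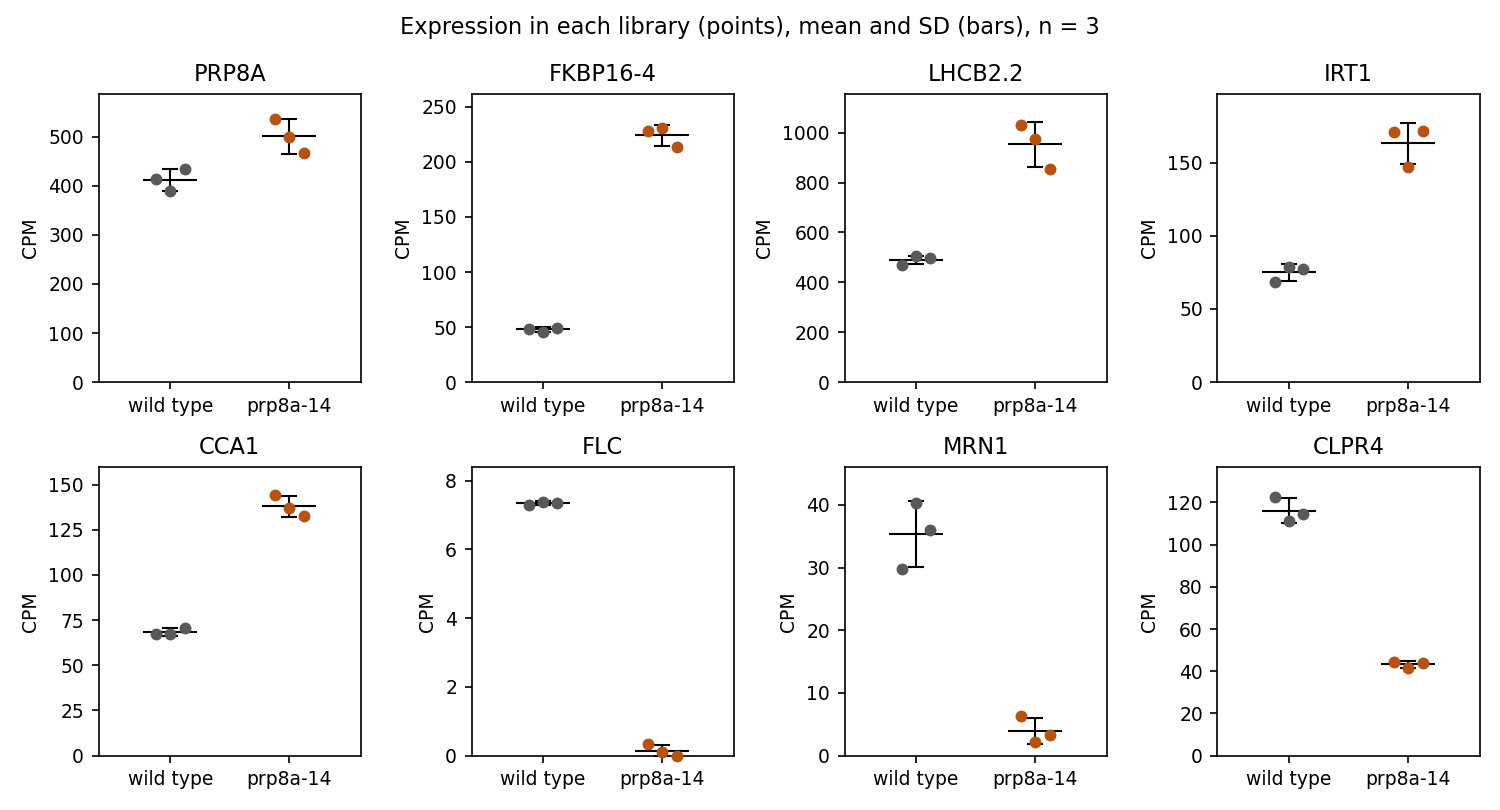
CPM (linear axes from 0) of 8 genes in each library, with wild type at left and prp8a-14 at right; points are libraries and bars the mean and SD of 3. FKBP16-4 rose from 47.8 to 224 CPM, and FLC lay at 0 in 1 mutant library.

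Within the poly-A selected RNA, plastid-encoded transcripts rose together in the mutant. Of 101 measured, 96 rose and 0 fell (97 and 0 adjusted over the list alone), with a median log2 change of 1.05, or 2.07-fold, and their share of counts went from 0.868% ± 0.0658 (SD, n = 3) to 1.79% ± 0.235 (SD, n = 3). CLPP1, the plastid-encoded Clp protease subunit, rose by 1.82, and the ribosomal protein genes RPL20, RPL32, RPL14 and RPS12A rose by 1.61, 1.52, 1.51 and 2.04. The mean change was 1.26 ± 0.353 (SD) over 36 genes of the plastid genetic system and 1.02 ± 0.280 (SD) over 43 photosynthesis genes. That difference of 0.244, a comparison chosen after the values were seen between genes that are not independent, ran from 0.0529 to 0.452 in single mutant libraries. The genetic system class includes ycf2-B, whose high value in replicate 6 (below) enters the class mean and that range. Plastid ycf2-B also passed the threshold, but replicate 6 alone held 30.7 CPM against 1.72 and 2.29 in the other mutant libraries, the log2 change was 1.02 without it against 2.34, the call was lost without any 1 wild type library, with limma without trend, with both voom fits and with a pseudocount of 1 CPM, and its reads can be shared with its copy in the inverted repeat. Nuclear photosynthesis genes rose as well: 30 of 32 rose and 0 fell (30 and 0 adjusted over the list alone), with a median of 0.60. The antenna genes LHCB2.1 and LHCB2.2 rose by 0.94 and 0.96, whereas the Rubisco small subunit genes RBCS1B and RBCS2B had changes of 0.06 and 0.01 that did not pass. The other listed Rubisco small subunit genes, RBCS1A and RBCS3B, rose. Copies of the LHCB1, LHCB2 and RBCS genes are alike, so their single values are uncertain. Camera with BH gave an adjusted p = 2.7e-39 for the plastid list and 9.6e-21 for the nuclear one; both had an adjusted p = 0.35 with an estimated correlation. With quantile normalization the nuclear median was 0.30. Of 20 mitochondrion-encoded genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), and an adjusted p = 0.52 by camera with BH; that gene was ORF199 (1.17). Their median was 0.12, and -0.03 without wild type replicate 2, 0.02 without mutant replicate 6, 0.22 with quantile normalization and 0.03 with library totals.

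**Figure D2:**
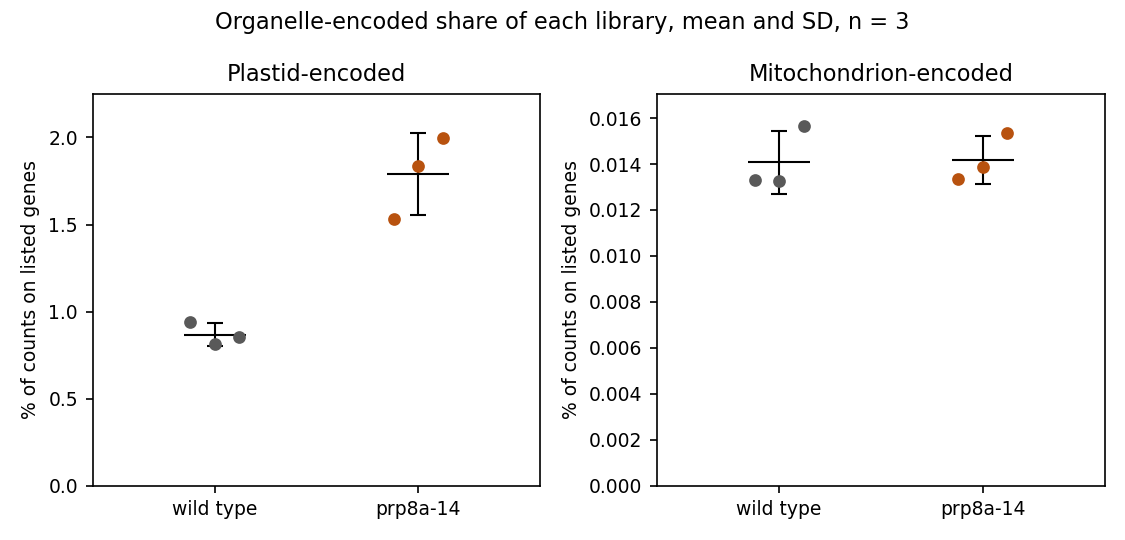
Share of the counts on listed genes (percent, linear axes from 0) that came from plastid-encoded (left) and mitochondrion-encoded (right) genes; points are libraries and bars the mean and SD of 3. The plastid share was 0.868% in wild type and 1.79% in prp8a-14, and the mitochondrial share 0.0141% and 0.0142%.

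Genes of the splicing machinery moved little. Of 40 core spliceosome and U snRNP genes 15 rose and 3 fell (19 and 3 adjusted over the list alone), with a median of 0.10. RDM16, a U4/U6 snRNP protein, rose by 0.35, and the U6-associated LSM8, LSM7 and LSM5 had falls of -0.40, -0.27 and -0.24. The list's adjusted p was 0.0089 by camera with BH, with an adjusted p = 0.35 with an estimated correlation; it was 0.099 with quantile normalization and 0.17 with library totals (medians of 0.06 and 0.01). Among 25 SR proteins and other regulators 6 rose and 5 fell (7 and 5 adjusted over the list alone): RS31A rose by 0.49 and PTB3 by 0.21, while the glycine-rich RNA-binding proteins GRP7 and GRP8 dropped by 0.44 and 0.38. PTB3 lost its call with library totals (0.12, adjusted p = 0.071, limma with BH), and GRP7 dropped by 0.74 with quantile normalization. Camera put that list up (adjusted p = 0.74) and fry down, so it has no direction. Of 8 genes of nonsense-mediated decay and the exon junction complex 1 rose, UPF3 (0.14), and 0 fell (0 and 0 adjusted over the list alone; camera with BH, adjusted p = 0.74). The UPF3 call was lost without wild type replicate 1, 2 or 3 and without mutant replicate 5 or 6, and with quantile normalization, limma without trend and library totals. LSM7 lost its call without wild type replicate 1 (adjusted p = 0.054, limma with BH).

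**Figure D3:**
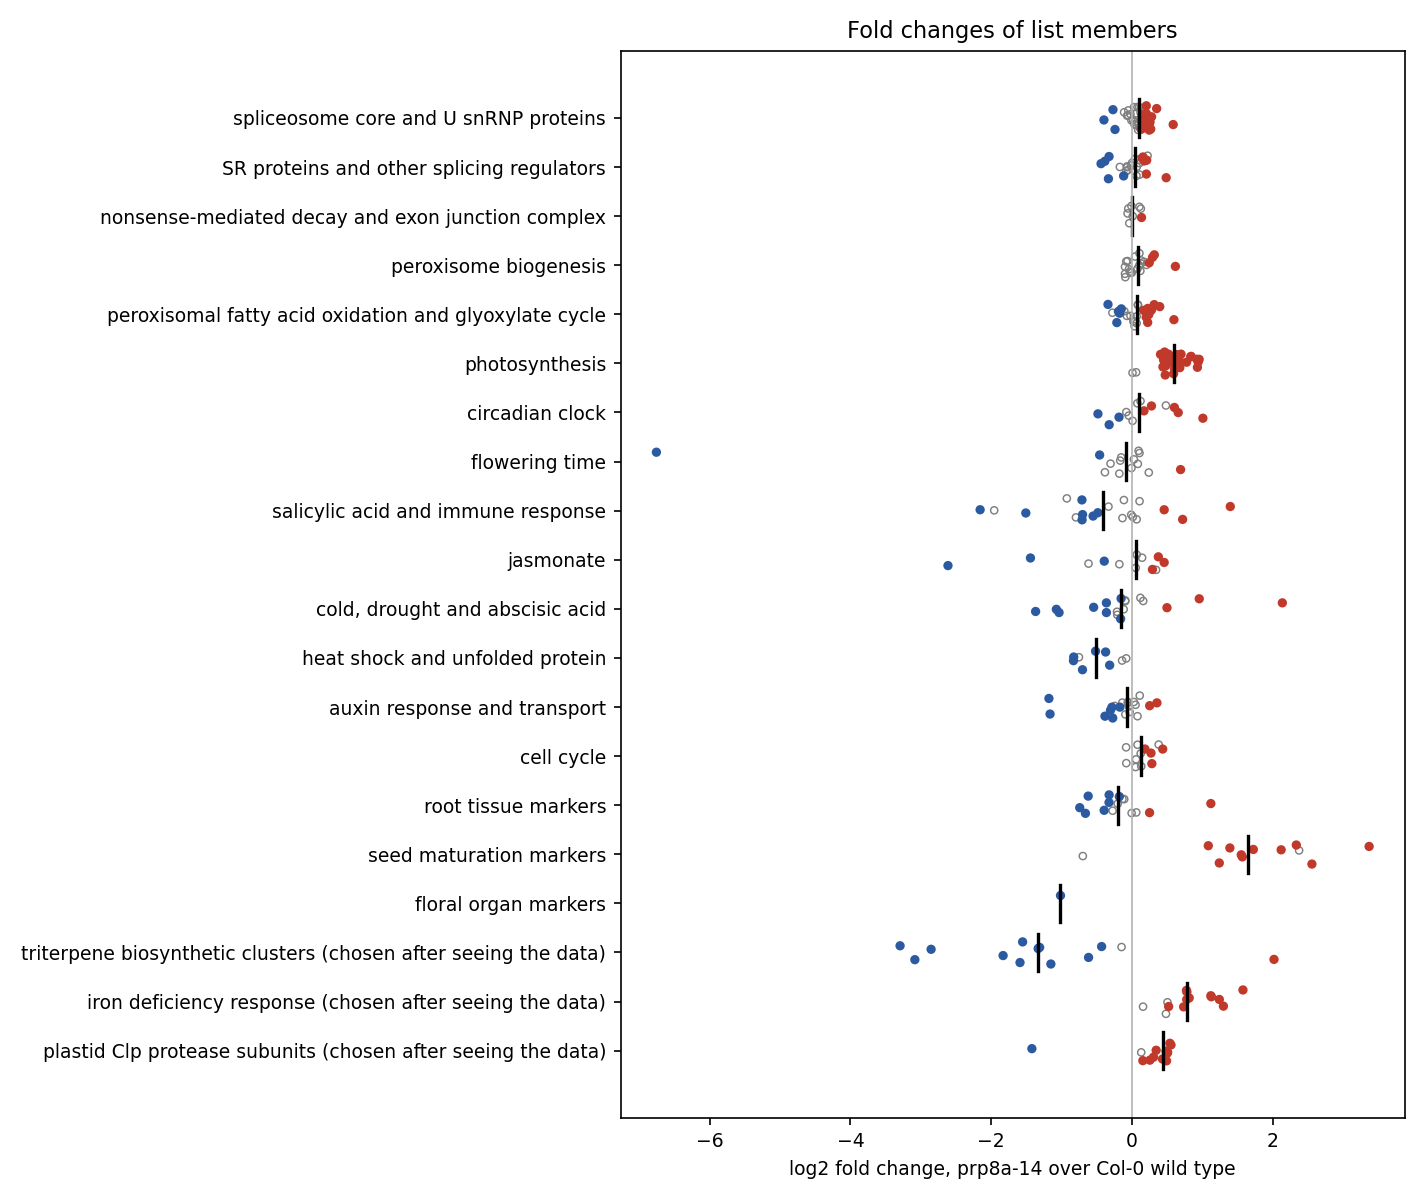
Fitted log2 fold change (prp8a-14 over wild type) of the members of 20 lists, 1 point per gene; filled points passed an adjusted p of 0.05 (red up, blue down), open points did not, and black lines are list medians. The photosynthesis median lies at 0.60 and the triterpene median at -1.33.

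Of 22 genes of peroxisome biogenesis 4 rose and 0 fell (4 and 0 adjusted over the list alone). Of 26 genes of peroxisomal fatty acid oxidation and the glyoxylate cycle 10 rose and 5 fell (10 and 5 adjusted over the list alone). The malate synthase MLS rose by 0.60 and the thiolase KAT2 by 0.40, and LACS7 and ACX3 dropped by 0.34 and 0.21. Neither list passed camera with BH (adjusted p = 0.16 and 0.20, and 0.48 and 0.65 with an estimated correlation). Fry, which tests a list against no change, put both up (adjusted p = 0.0029 and 0.042). The list medians were 0.09 and 0.07, but -0.0035 and -0.027 with library totals, so a rise against no change depends on the authors' scaling. With library totals the median over all genes was itself -0.091.

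FLC, the repressor of flowering, was nearly lost from the mutant. Its counts were 385, 387 and 416 in wild type and 18, 5 and 0 in prp8a-14, a pooled ratio of 52.5-fold (exact 95% counting interval 34.8 to 83.2; limma with BH, adjusted p = 0.00028). The ratio was 160 without mutant replicate 4 and 32.7 without 6. Its relative FLM fell by 0.46 and CO rose by 0.69; these were the 1 that rose and 2 that fell of 14 flowering genes (1 and 2 adjusted over the list alone; camera with BH, adjusted p = 0.48). FT and SOC1, targets further down the pathway, had changes of 0.24 and 0.03 that did not pass. Of 14 clock genes 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera with BH, adjusted p = 0.21): CCA1 doubled from 68.5 CPM ± 2.08 to 138 CPM ± 5.71 (SD, n = 3), PRR7 rose by 0.66, and ELF4 and FKF1 dropped by 0.48 and 0.32. Of 12 cell cycle genes 4 rose, among them CYCB2;2 (0.44) and KN (0.28), and 0 fell (5 and 0 adjusted over the list alone). The cell cycle list did not pass camera with BH (adjusted p = 0.10). Under the alternatives the lowest rise of KN was 0.19.

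Heat shock and unfolded protein genes fell: 6 of 9 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.52. HSP70-4 dropped by 0.83, as did BIP3 at low counts; BIP3 lost its call without wild type replicate 3 or mutant replicate 4. Camera with BH gave an adjusted p = 0.0010, and an adjusted p = 0.35 with an estimated correlation. Among 20 salicylic acid and immune genes 3 rose and 7 fell (3 and 7 adjusted over the list alone). The receptor kinase gene FRK1 dropped by 2.16 and the glucanase gene PR2 by 1.51, and CYP71A13, an enzyme of camalexin synthesis, rose from 9.30 CPM ± 0.191 to 24.7 CPM ± 4.11 (SD, n = 3). WRKY33 rose by 0.72 (limma with BH, adjusted p = 0.0496), with overlapping groups, and lost its call without wild type replicate 1 or 2 or mutant replicate 5 or 6 and in 5 other alternatives; its change was 1.12 without mutant replicate 4 and 0.42 without 6. The list did not pass camera with BH (adjusted p = 0.081), but passed without wild type replicate 2 (0.018) or mutant replicate 6 (0.034), with an adjusted p = 0.65 with an estimated correlation and all libraries. In the jasmonate list of 12 genes 3 rose and 3 fell (4 and 4 adjusted over the list alone): VSP1 and VSP2 dropped by 2.61 and 1.44, and JAZ1 and AOS rose by 0.46 and 0.38. JAZ1 lost its call in limma without trend (adjusted p = 0.072). The list did not pass camera with BH (adjusted p = 0.74).

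Of 18 measured cold, drought and abscisic acid genes 3 rose and 8 fell (3 and 8 adjusted over the list alone). KIN1 dropped by 1.07 and COR15A by 1.37, whereas CBF2, an activator of the cold genes, rose from 0.620 CPM ± 0.441 (SD, n = 3) with a pooled ratio of 3.82 (exact 95% counting interval 3.06 to 4.80; 6.34 without wild type replicate 3), and RD29B rose by 0.96. COR15A lost its call without wild type replicate 3 and in limma without trend. The list's adjusted p was 0.069 (camera with BH); the list passed at a mean of at least 5 CPM (0.012), with fry (0.0040) and without mutant replicate 5 (0.045), with an adjusted p = 0.35 with an estimated correlation. Of 20 auxin genes 2 rose and 7 fell (2 and 7 adjusted over the list alone; camera with BH, adjusted p = 0.13, and 0.038 without mutant replicate 4, with an adjusted p = 0.67 with an estimated correlation and all libraries). The early auxin response genes IAA19 and IAA5 dropped by 1.16 and 1.18, and the efflux carrier gene PIN3 and the receptor gene TIR1 rose by 0.36 and 0.25 (TIR1 0.16 with library totals). IAA5 lost its call without wild type replicate 2.

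Seed maturation genes were higher in the mutant at low levels. Of 12 measured 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.65; camera with BH gave an adjusted p = 0.0010, and an adjusted p = 0.51 with an estimated correlation. At a mean of at least 5 CPM 1 member was left and the call was lost (adjusted p = 0.37), and with a pseudocount of 1 CPM the median was 0.66. Their summed level was 6.92, 11.5 and 6.78 CPM in wild type and 31.3, 19.4 and 18.5 CPM in prp8a-14. The seed regulator ABI3 rose by 1.73, and the storage protein genes CRC and SESA3 rose with pooled ratios of 6.84 (exact 95% counting interval 4.98 to 9.61) and 5.68 (3.59 to 9.38). CRC held 3.64 CPM in replicate 4 against 0.614 and 1.23 in the others, and its ratio was 3.54 without that library and 11.3 without wild type replicate 2. The SESA3 ratio was 14.0 without wild type replicate 1 and 3.70 without 3. SESA3 lost its call without mutant replicate 4 or 6, and both lost it in limma without trend (adjusted p = 0.051 and 0.093). Root tissue markers gave 2 that rose and 7 that fell of 15 (2 and 7 adjusted over the list alone), with a median of -0.20, or -0.31 without wild type replicate 1 (camera with BH, adjusted p = 0.10). The Casparian strip gene CASP1 and the root hair regulator RHD6 dropped by 0.74 and 0.66, while the iron transporter gene IRT1 rose by 1.12 and SCR by 0.25 (SCR 0.16 with library totals). These root and seed shifts stood beside the rise of the photosynthesis lists. SEP3, the 1 floral marker measured of 7 listed, fell by 1.02 (1 fell and 0 rose adjusted over the list alone; camera with BH, adjusted p = 0.31), and lost its call without wild type replicate 2 or 3.

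Of 187 cytosolic ribosomal protein genes 2 rose and 24 fell (0 and 15 adjusted over the list alone), with a median of -0.05; the 2 that rose, RPS13B and RPL18AC, moved by 0.12 each and lost their calls in most sets with a library left out and with quantile normalization, limma without trend and library totals. ARP2, a gene of ribosomal protein L3, fell by 1.02 and RPS16B by 0.81. Camera with BH gave an adjusted p = 0.0017, and an adjusted p = 0.67 with an estimated correlation; the call was lost with fry (adjusted p = 0.11), and the median was -0.03 without mutant replicate 5, -0.11 with quantile normalization and -0.15 with library totals. Of 3084 genes with 1 exon 492 rose and 506 fell (475 and 492 adjusted over the list alone), and of 3860 genes with at least 10 exons 752 rose and 644 fell (758 and 650 adjusted over the list alone; both lists camera with BH, adjusted p = 0.74). Spearman's rho of fold change and exon number across 19686 nuclear genes, which are not independent replicates, was 0.0357 and 0.00168 given transcript length; over the 9 pairs of libraries rho had an SD of 0.0206. For the absolute change rho was -0.133, and -0.102 at a mean of at least 5 CPM (smaller absolute changes in genes with more exons). Changes of at least 2-fold were found in 1.04% (up) and 1.72% (down) of genes with 1 exon, against 0.311% and 0.751% of genes with at least 10 exons. These shares were not adjusted for expression level or length. A mean of at least 5 CPM was reached by 1944 of the 3084 genes with 1 exon and 3523 of the 3860 with at least 10. The rule also named genes in these lists that went nearly from off to on or back. AT5G27010 had 0, 3 and 4 counts in wild type and 553, 520 and 744 in prp8a-14, a pooled ratio of 255 (exact 95% counting interval 124 to 636). AT3G28520, AT3G60176 and AT4G15040 had ratios of 122 (51.8 to 376), 46.3 (24.97 to 97.3) and 30.2 (20.1 to 47.5). Without wild type replicate 3 the ratios of AT5G27010, AT3G28520 and AT3G60176 were 388, 198 and 30.2, and that of AT3G60176 was 78.3 without wild type replicate 2. In the other direction the pooled ratio of wild type to mutant was 15.4 (10.97 to 22.4) for the auxin response factor gene ARF20, and 7.28 and 4.51 for the low-sulfur response genes LSU1 and LSU3.

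Genes close to PRP8A were not called more often than others. Within 2 Mb of it 187 of 512 genes changed (36.5%), against 6692 of 19173 elsewhere (34.9%; Fisher's exact test, two-sided, odds ratio 1.07, p = 0.45). An adjusted p under 0.05 was given to 7409 genes in the authors' deposited table, 3777 higher and 3632 lower in the mutant. Of these 6791 were also called here, and all 6791 had the same direction. Spearman's rho of the fold changes across genes was 0.996. Both fits rest on the same libraries, so this match is not independent evidence.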

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

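Without any 1 library, 5405 to 6416 genes changed and 419 to 484 by at least 2-fold; 4 to 5 of the 17 fixed lists, 2 of 5 annotation lists and 78 to 83 named genes passed (86 with all libraries). PRP8A kept its rise in every alternative run (0.23 to 0.33 without a library, 0.20 with quantile normalization, 0.18 with library totals). No paired analysis was possible because the genotypes share no replicate numbers. Changes of at least 2-fold numbered 226 with a mean of at least 5 CPM, where fewer genes are tested, and 235 with a pseudocount of 1 CPM, which shrinks low genes. Lists that passed numbered 4 and 2 with the preset correlation, 0 and 0 with an estimated correlation (camera; unadjusted p under 0.05 for 1 and 1), and 14 and 2 with fry (also both peroxisome lists, clock, flowering, immune, jasmonate, cold, cell cycle, root, floral and single-exon genes, but not ribosomal proteins); without organelle-encoded genes, which removes the plastid list, 1 annotation list passed. Spearman's rho with exon number was 0.0146 at a mean of at least 5 CPM, and the odds ratio near PRP8A was 0.957 at 5 Mb; the cause was not tested. The lists that changed direction never passed camera. With quantile normalization adjusted p was 0.807 for SR proteins and 0.707 for nonsense-mediated decay, single-exon and many-exon genes. With library totals it was 0.779, 0.608, 0.655 and 0.655, and 0.974 for jasmonate. With fry it was 0.808 for SR proteins. For these the cause was not tested. Of the values of single named genes under the alternatives, 1193 kept direction and side of the threshold, 56 lost the call and none changed direction. Genes near the floor are limited by depth: 3 counts are 0.0484 to 0.0635 CPM. The voom fits and library totals were chosen after seeing the data.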

Other observations

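The lists of triterpene, iron and Clp genes, the tests of neighbouring genes and of sequence shared between them, the test of poly-A selection and that of green tissue as the whole of the plastid rise were chosen only after the results were seen. Genes of the iron deficiency response rose in prp8a-14: 11 of 14 measured rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 change of 0.78. The ferric reductase gene FRO2 rose by 1.24, the transporter gene IRT1 by 1.12, the regulator genes FIT and BHLH100 by 0.78 and 1.13, and MYB72 by 1.58. Of 13 genes of the plastid Clp protease 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.44 (0.28 with quantile normalization): CLPR1, CLPR3 and CLPT1 rose by 0.49, 0.54 and 0.56, and the 1 that fell was CLPR4, from 116 CPM ± 5.91 to 43.3 CPM ± 1.62 (SD, n = 3). These lists were picked from these data, so their counts are not independent evidence; camera with BH gave an adjusted p = 6.8e-09 for iron and 8.4e-07 for Clp, and an adjusted p = 0.15 for both with an estimated correlation.

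Genes of triterpene synthesis that lie in clusters on the chromosomes fell: 11 of 13 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -1.33 (camera with BH, adjusted p = 4.3e-09, and an adjusted p = 0.15 with an estimated correlation). In the thalianol cluster THAS1, CYP708A2, CYP705A5 and BAHD1 dropped by 1.83, 1.59, 1.33 and 1.55, and in the marneral cluster MRN1, CYP71A16 and CYP705A12 dropped by 3.29, 1.15 and 1.31. The gene that rose was the baruol synthase gene BARS1, by 2.02. The root markers did not settle whether a smaller share of root tissue was the whole cause. Their median was -0.202 and their lower quartile -0.36 (-0.49 with quantile normalization). The rule set beforehand against this cause asked for a median above -0.25 and a lower quartile above the triterpene median. These values met it. The median did not meet that rule without wild type replicate 1 (-0.31) or mutant replicate 5 (-0.25). Nor did it at a mean of at least 5 CPM (-0.27) or with library totals (-0.30). The summed level of the root markers was 4367, 4553 and 4120 CPM in wild type and 3689, 3733 and 3777 CPM in prp8a-14. Of the markers 7 fell and 2 rose, among them IRT1 (1.12), which is also in the iron list. A smaller root share may still contribute. The markers mix root hair, Casparian strip and other root genes, so they cannot test a loss of particular root cells. Reads shared between near-identical tandem copies are argued against by sequence: 5.71% of neighbouring pairs (2 of 35) shared at least 10% of their 50-base words. By description 31.4% of pairs shared a family. That share misses related pairs such as MLP328 and MLP329 or LSU3 and LSU1, so it cannot decide the question. Neighbours fell together more often than in random sets: the 295 nuclear genes that fell by at least 2-fold formed 35 neighbouring pairs against a mean of 4.35 in 10000 random sets (one-sided permutation test, p = 0.0001, the smallest they can give). The 107 nuclear genes that rose by at least 2-fold did so too, with 5 pairs against 0.57 (one-sided permutation test, p = 0.0005), so this is not particular to the falls. The random sets did not keep related genes side by side. The 35 pairs also include pairs of the thalianol and marneral clusters, which were seen before the test. The excess therefore cannot tell shared control of neighbours from related genes that respond alike. An effect of the genotype on these pathways stays open.

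The rise of plastid-encoded transcripts was weighed against technical causes. More RNA without a poly-A tail passing the selection is argued against by the 20 listed mitochondrion-encoded genes. Their upper quartile of 0.272 lay below the plastid lower quartile of 0.87. The comparison is sparse: these genes held 0.0141% of counts in wild type and 0.0142% in the mutant, and 3 reached a mean of 5 CPM. It covers a change shared by both organelles, not one in the tails of plastid RNA alone. The authors' scaling is argued against as well, since the plastid median was 0.955 with library totals. A larger share of green tissue may account for part of the plastid rise: the median of nuclear photosynthesis genes was 0.568 of the plastid median. That met the rule set beforehand. With quantile normalization the rule was not met: the nuclear median was 0.30 against 0.60, and the plastid median was 1.07. Of the 32 nuclear genes 30 rose, among them the Rubisco genes RBCS1A and RBCS3B, but the Rubisco genes RBCS1B and RBCS2B did not pass. As the whole of the rise a larger green share is argued against, because the nuclear upper quartile of 0.686 lay below the plastid lower quartile. An effect of the genotype on plastid transcripts stays open.

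The weak relation of fold change to exon number (rho 0.0357) may reflect gene length or expression level. Given transcript length the correlation was 0.047 of its raw value, and in 2 of 4 equal expression bins its sign was the opposite. What each cause would show was set down before these results were seen, but was taken out once the raw correlation and that given length were known, and then put back in the same words.

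All 10 splits of the 6 libraries into groups of 3 were fitted with limma. As many changed genes as the real 6977 were found in 1 of 10, the real split, and the highest other gave 0; as many changes of at least 2-fold as the real 461 were found in 1, and the highest other gave 0. The other splits gave 182 to 505 genes at an unadjusted p under 0.05, against 8836. With 10 splits the share cannot go under 0.05. Each of the other splits mixed the genotypes, so the genotype difference widened the spread within its groups and lowered its calls. Their counts therefore do not measure the noise of the method.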
